A study of Mus musculus with 21 samples.

How the data were processed

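Chromatin accessibility was measured with Omni-ATAC, a transposase-based assay of open chromatin, in 21 mouse libraries that fall into 7 groups of 3. The primary samples were EGFP-positive cells sorted from Atoh1-EGFP cerebella. They comprised granule neuron progenitors (GNP) taken at postnatal day 7, whose sample titles read Ptch1GNP and whose genotype is not given in the sources used here, hyperplasia at postnatal day 28 and medulloblastoma tumors. The other libraries came from VDR, which the labels describe as a mouse medulloblastoma cell line. VDR cells were untreated, or treated with a control siRNA (siNC), an siRNA against Nfia (siNfia) or an siRNA against Nfib (siNfib). The labels and the series design say siRNA, while the names of the deposited lists begin with sh, so the reagent is not certain. The labels do not say whether the replicates of a group came from separate animals or separate cultures, so a p-value here may reflect technical spread alone.

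The deposited data are 1 list of peak summits per library, each with a score read as the peak caller's -log10 of a p or q value (unit neg_log10_p). The authors do not state which, nor the threshold at which peaks were called. The submitters' processing notes name Bowtie2, Picard and MACS2 with the mm10 genome, without versions or parameters. How reads were shifted, filtered or deduplicated is not given in the sources used here. Because the score depends on the depth of its own library, it was not compared between libraries as a measure of accessibility and served to rank or filter summits within a list. Read depth is unknown, and no counting interval could be given. The lists held between 159720 and 279584 summits, and the score at rank 100000 served with the list length as a stand-in for the signal strength of a library.

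To compare libraries at equal list length, the 100000 strongest summits on chromosomes 1 to 19, X and Y were kept from each. Kept summits of all libraries were merged greedily by rank into non-overlapping regions of 500 bp, and a region was called occupied in a library with a kept summit inside it. This gave 270959 regions. Between 79.3% and 86.6% of a library's kept summits lay inside a region, and the rest lay in the gaps between neighbouring regions and were not counted. Regions were assigned to the smallest protein-coding gene body that held their centre, or else to the nearest gene body within 100 kb, with the GRCm38.p6 annotation of 21887 genes, which is the mm10 assembly. This assignment replaced the nearest transcription start because the annotation used carries no strand, and for the same reason a position within 1 kb of either gene end replaced the promoter. By this rule 89.1% of regions were assigned to a gene and 56.0% lay in a gene body. Coordinates are 1-based on mm10. Sequence-motif shares were planned but no genome sequence was used here, so they were not analysed here.

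Gained and lost regions were those occupied in 3 of 3 libraries of one group and in 0 of 3 of the other. An unoccupied region may still hold a weaker summit of the whole list, so a gain or loss can be a shift in rank. Single regions were not tested, since 3 libraries against 3 cannot give an exact two-sided p below 0.1. Each total was instead set beside the totals of the other splits of the same 6 libraries. For genes, the number of occupied regions per gene was analysed as log2 of the count plus 1 with limma and its trended empirical Bayes variance. Genes with a mean under 3 regions were left out. The first fit held the 12 GNP, hyperplasia, tumor and untreated VDR libraries and tested 6875 genes. The second fit held the 12 VDR libraries and tested 6613 genes. The variance of a gene was taken over all groups of its fit, so the spread of groups outside a comparison enters its p-value. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 changes are differences of mean log2 values and SE is their standard error in the fit. In the text the ± sign gives the SD over 3 libraries.

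Fixed gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and list members were also counted with p adjusted over the list alone, a count given only where it differs from that over all genes tested. There were 17 lists: the NFI family, the Hedgehog pathway, granule progenitor genes, granule neuron differentiation, cell cycle, tumour suppressors, AP-1 and immediate early genes, neural stem and glial progenitor genes, chromatin regulators and Hox clusters. To these were added markers of other cell types, namely astrocytes, oligodendrocytes, microglia and immune cells, endothelial and mural cells, Purkinje cells and interneurons, fibroblasts and mesenchyme, and selectors of non-granule lineages. Lists with fewer than 3 tested members were counted but not tested with camera.

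The genes named in the text followed a fixed rule. In each comparison these are the 10 genes in each direction with the largest log2 change among those called whose replicate values did not overlap between groups, or all of them if fewer. Where none was called, the 3 in each direction with the smallest p are given as values only. To these were added up to 4 members of each fixed list with the largest change, and always Nfia, Nfib, Ptch1, Gli1 and Atoh1. From each comparison the 3 gained and 3 lost regions with the highest mean rank were named. A few items that the rule would name are not reported here. The comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Genes named outside the rule are marked as chosen after their values were seen.

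Similarity between libraries was the Jaccard index of occupied regions, tested one-sided by an exact permutation test over the 280 partitions of 9 libraries. Chromosome shares, positions relative to genes and the occupancy of tumor regions in siRNA-treated cells were tested with two-sided exact permutation tests and Benjamini-Hochberg adjustment within each family. Overlap between the knockdown comparisons was set against the product expected from independent sets.

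Alternatives covered the number of summits kept, the whole deposited lists, a score of at least 10, windows of 200 and 1000 bp, a gene distance of 20 kb, a pseudocount of 0.5, the square root of the count, no filter on low genes, the replicate number as a block, and each library left out in turn. Others were added after the data had been seen: centring each gene on its 51 neighbouring genes along the chromosome, leaving out chromosome 6, fitting only the 9 primary or only the 9 siRNA libraries, using siNC-treated cells in place of untreated VDR cells, and leaving out libraries from the knockdown overlap. Replicate numbers did not pair libraries across groups: correlations between libraries of the same number ran from -0.035 to 0.079, and 7 of 18 libraries correlated best with a library of their own number.

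The gene fit was tested on simulated data with 200 changed genes. At a fold of 1.5 it recovered 19.4%, 16.4% and 14.9% of changed genes for hyperplasia against GNP, siNfia against siNC and siNfib against siNC. At a fold of 2 it recovered 44.8%, 55.2% and 47.8%, and at a fold of 3 it recovered 83.3%, 86.4% and 84.8%. In these simulations 1, 4 and 5 unchanged genes were called. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.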

Results

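Accessible chromatin was profiled in 21 mouse libraries to follow medulloblastoma from its progenitor cells to tumors and to ask what knockdown of the NFI transcription factors Nfia and Nfib does in a medulloblastoma cell line, VDR. There were 3 libraries each of GNP, whose titles carry the prefix Ptch1, and of hyperplasia and tumor cells, and 3 each of untreated, siNC-treated, siNfia-treated and siNfib-treated VDR cells. Each library was a list of peak summits with a score, and its read depth is unknown. The lists averaged 229494 ± 26064 summits in GNP, 226692 ± 12285 in hyperplasia and 219497 ± 38006 in tumor (SD, n = 3 libraries here and below). VDR lists averaged 177565 ± 17242 summits in untreated cells, 214421 ± 19028 with siNC, 184984 ± 14865 with siNfia and 234667 ± 39355 with siNfib. The score at rank 100000, a stand-in for signal strength, was 20.1 ± 7.62 in GNP, 10.5 ± 1.83 in hyperplasia and 14.4 ± 6.05 in tumor. It was 3.86 ± 0.107 in untreated VDR cells, 6.84 ± 2.45 with siNC, 5.92 ± 1.16 with siNfia and 11.3 ± 5.27 with siNfib.

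Of the 270959 regions, 40246 were occupied in all 9 primary libraries, 14732 in all 21 and 132246 in only 1 library. Libraries of one primary stage shared more regions with each other (mean Jaccard index 0.750) than with other stages (0.644; exact one-sided permutation p = 0.00357, the smallest that 280 partitions allow). The siRNA libraries also shared more within a treatment (0.661) than between treatments (0.597; exact one-sided permutation p = 0.00357, again the smallest possible). That excess of 0.0644 was 0.0411, 0.0411 and 0.0423 without siNfib replicate 1, 2 or 3. The mean index was 0.807 within GNP, 0.702 within hyperplasia and 0.742 within tumor. It was 0.614 within siNC and 0.631 within siNfia, close to the 0.60 between these treatments, 0.740 within siNfib, but 0.226 within untreated VDR cells, below the 0.249 between untreated VDR and tumor and the 0.282 between untreated VDR and siNC. Sites within 1 kb of a gene end made up 32.0 ± 0.466% of kept summits in GNP, 30.2 ± 1.5% in hyperplasia, 29.5 ± 0.550% in tumor and 19.2 ± 1.59% in untreated VDR cells. The 3 primary stages did not pass the test for this share (exact permutation p = 0.075, adjusted p = 0.129), and neither did the siRNA groups at 30.4 ± 1.94%, 30.1 ± 0.776% and 32.0 ± 0.706% for siNC, siNfia and siNfib (exact permutation p = 0.218, adjusted p = 0.245).

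**Figure D1:**
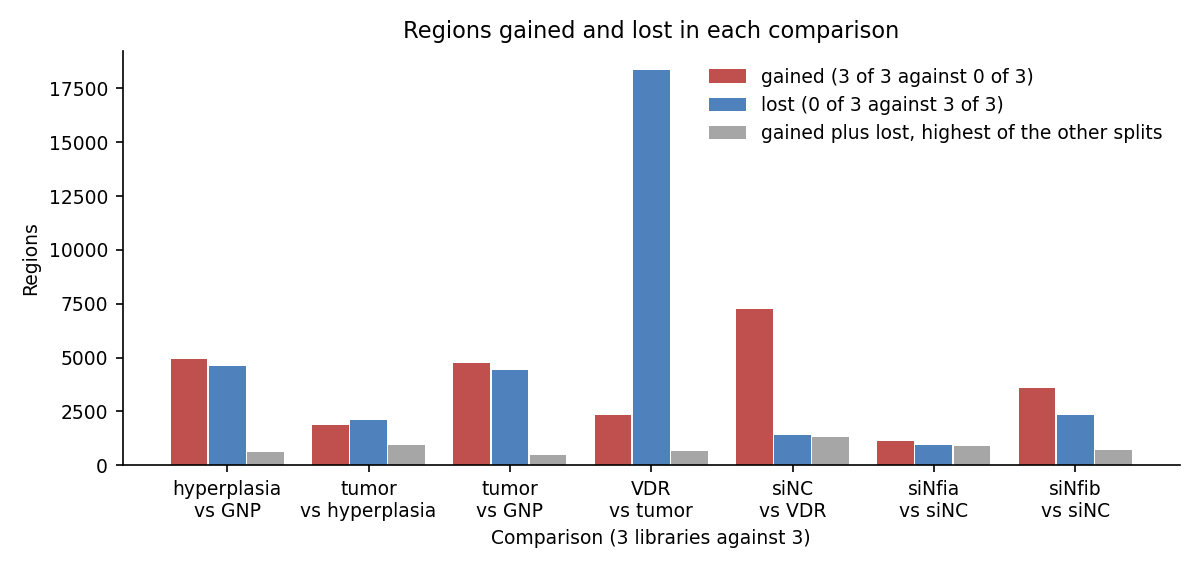
Number of regions (vertical axis) gained and lost in each comparison of 3 libraries against 3 (horizontal axis), with the highest total among the other splits of the same 6 libraries in grey. Totals ran from 2080 for siNfia against siNC, where the highest other split gave 920, to 20684 for untreated VDR against tumor, where it gave 678.

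Hyperplasia at postnatal day 28 was compared with GNP at postnatal day 7 to see which chromatin differed before tumors formed. Every library of a stage had the same age, so stage cannot be told apart from age. Hyperplasia lists were also weaker, with a score at rank 100000 of 9.26 to 12.6 against 15.3 to 28.9 in GNP. Stage therefore cannot be told apart from signal strength either. The GNP genotype is not given, so genotype may differ as well. Hyperplasia cells had more occupied regions over Fancc, a Fanconi anaemia gene, with 14.3 ± 1.15 against 4 ± 0 in GNP. Its neighbour Aopep had 17.3 ± 1.15 against 5 ± 1.73. Both genes lie beside Ptch1 on chromosome 13. Regions over Kif21a, a neuronal kinesin, rose from 1 ± 0 to 7 ± 1, those over Hpgds, a prostaglandin D synthase, from 0.333 ± 0.577 to 5 ± 1, and those over the midbrain and floor-plate factor Foxa2 from 5.67 ± 0.577 to 15.7 ± 2.89. Fewer regions were occupied over Tlx3, a homeobox gene of excitatory neurons, with 2 ± 0 against 8.33 ± 1.53 in GNP. Gsdmd, the pore-forming gasdermin D, had 1.33 ± 0.577 against 6 ± 0. The Hedgehog genes Ptch1 (18.7 ± 1.15 against 17.7 ± 2.52) and Gli1 (5.67 ± 0.577 against 7 ± 0) and the progenitor factor Atoh1 (8.33 ± 0.577 against 10 ± 1) did not pass the test (adjusted p = 0.854, 0.444 and 0.47). The same held for Nfia (66 ± 0 against 60.7 ± 0.577, adjusted p = 0.834) and Nfib (48.3 ± 3.06 against 51.7 ± 4.04, adjusted p = 0.784). Nfia values did not overlap between hyperplasia and GNP. Its p-value also holds the spread of the other groups in the fit, with an SD of 9.07 in tumor and 8.74 in untreated VDR cells. It therefore does not show that Nfia was unchanged.

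Other genes that gained regions in hyperplasia were Saxo1 (log2 change 1.77), the phosphotyrosine-binding gene Pid1 (1.60), Bcas3 (1.59), Dnajc5b (1.58), the collagen gene Col28a1 (1.57) and Serpinb5, which had 2 ± 1 regions and was listed at 0 in GNP. Regions fell at the spectrin gene Sptbn5 (log2 change -1.74), the potassium-channel partner Dpp10 (-1.41), the stanniocalcin gene Stc1 (-1.40), the bradykinin receptor Bdkrb2 (-1.20), Cpne4 (-1.14), the metalloproteinase Adamts18 (-1.11) and Zdhhc25 (-1.09). Zfp982 had 1.67 ± 0.577 regions in GNP and was listed at 0 in hyperplasia. Adjusted p-values were 7.92e-05 for Kif21a, 0.000399 for Fancc and 0.00617 for Hpgds, Aopep, Pid1, Bcas3, Tlx3, Gsdmd, Dpp10 and Foxa2. With 50000 summits per list the Dpp10 value was 0.33, the opposite sign. Saxo1, Serpinb5, Sptbn5, Dpp10, Zfp982 and Foxf1 had enough regions to be tested only because the VDR libraries were in the fit.

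Among the fixed lists, the Hedgehog pathway had 1 of 19 tested members up and 0 down, and 2 up and 0 down when adjusted over the list alone. The member was Foxf1, a mesenchymal forkhead gene (2.67 ± 0.577 against 0.333 ± 0.577 regions, adjusted p = 0.0244), and the list's median of -0.08 and downward test differ in sign from its mean of 0.024. Of the markers of other cell types, 1 of 6 astrocyte, 1 of 3 microglia, 1 of 6 Purkinje and interneuron, and 1 of 11 non-granule lineage genes rose and 0 fell. These were the glial glutamate transporter Slc1a3 (19.7 ± 2.08 against 14 ± 1, adjusted p = 0.0422), the myeloid factor Irf8 (11.7 ± 1.53 against 6.33 ± 1.15, adjusted p = 0.0437), the Purkinje-cell factor Foxp2 (18.7 ± 0.577 against 8.33 ± 1.15, adjusted p = 0.0454) and Foxa2. The calls of Slc1a3, Irf8 and Foxp2 ended whichever of the GNP or hyperplasia libraries was left out (adjusted p from 0.0688 to 0.172, 0.0816 to 0.164 and 0.125 to 0.167), and that of Foxf1 with any but GNP replicate 3 left out (adjusted p from 0.0611 to 0.115). With neighbouring genes as the baseline, the Slc1a3 change was 0.29 (adjusted p = 0.21) and the Foxp2 change 0.85 (adjusted p = 0.054). Adjusted over the list alone, 1 oligodendrocyte gene of 6 and 2 microglia genes of 3 rose, and 0 of 1 Hox gene rose while 1 fell. The other lists had 0 genes up and 0 down by limma: 4 NFI, 18 granule progenitor, 24 granule neuron, 10 cell cycle, 11 tumour suppressor, 14 AP-1, 10 neural stem, 6 oligodendrocyte, 6 endothelial, 11 fibroblast, 1 Hox and 15 chromatin genes were tested. No list passed camera, where the lowest adjusted p was 0.126 for microglia. The tumour suppressor list also had a median and test below 0 and a mean above it.

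Regions moved in larger numbers than genes, with 4942 gained and 4635 lost, or 2651 gained and 9542 lost at a score of at least 10. A gained region in Pid1 lay at chromosome 1, 84222045 to 84222544, another 67905 bp from Setd4 at chromosome 16, 93515302 to 93515801, and the last in the translation-factor gene Eif4g3 at chromosome 4, 138084826 to 138085325. The region near Setd4 was absent from the whole lists of all 3 GNP libraries. The lost regions of highest rank lay 22189 bp from Pgm1 at chromosome 4, 100009233 to 100009732, and away from any gene at chromosome 12, 5996645 to 5997144, and chromosome 7, 51307704 to 51308203. In tumor libraries 58.5 ± 0.973% of the gained regions were occupied, and 30.4 ± 4.17% of the lost ones.

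By limma, 83 genes rose and 55 fell of 6875 tested, against 1123 at an unadjusted p under 0.05. Replicate values did not overlap in 21.9% of genes, where chance gives at most 10%. Tied counts were taken as overlap here and below, which lowers the chance value by an amount not computed. The count of 138 was 5 in the whole lists, which shared 0 of the 138, and 136 at 50000 summits, which shared 18. At a score of at least 10, which leaves list lengths unequal, 4 genes rose and 128 fell. The count was 17, 16 and 20 without GNP replicate 1, 2 or 3 and 33, 26 and 23 without hyperplasia replicate 1, 2 or 3, while fitting the 9 primary libraries alone gave 728. Of the 25 called genes named here, 11 stayed called whichever library was left out: Aopep, Bcas3, Bdkrb2, Dpp10, Fancc, Foxa2, Gsdmd, Hpgds, Kif21a, Pid1 and Tlx3.

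The comparison of tumor with hyperplasia covers the last step of tumor formation, and 1 gene passed its test. No age is listed for the tumor libraries, so age may differ here too. Gli3, which encodes the main repressor among the Hedgehog transcription factors, lost regions from 14.3 ± 2.52 in hyperplasia to 3 ± 0 in tumor (log2 change -1.93, SE 0.14, adjusted p = 7.86e-05). GNP had 11.7 ± 0.577 regions over Gli3, and VDR cells had 0 untreated, 0.333 with siNC, 0.333 with siNfia and 0 with siNfib. The loss was called in the whole lists and whichever library was left out. At 50000 summits Gli3 had no value, so the call could not be checked there. Atoh1 had 12.3 ± 2.08 regions in tumor against 8.33 ± 0.577 (adjusted p = 0.207), Ptch1 19.7 ± 3.06 against 18.7 ± 1.15 (adjusted p = 0.966) and Gli1 6.67 ± 0.577 against 5.67 ± 0.577 (adjusted p = 0.773). Nfia had 62.7 ± 9.07 against 66 ± 0 (adjusted p = 0.966) and Nfib 50.3 ± 7.02 against 48.3 ± 3.06 (adjusted p = 0.97).

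Fitting the 9 primary libraries without the VDR line called 90 genes up and 80 down from hyperplasia to tumor. The genes named from that fit were chosen after their values were seen. Lratd1 went from 5.67 to 0.333 regions (log2 change -2.39, adjusted p = 0.0103), the neural-crest factor Pax3 from 6.33 to 0.667 (-2.34, adjusted p = 0.0397), and the Wnt antagonist Frzb from 5.33 ± 0.577 to 2 ± 0 (-1.07, adjusted p = 0.000204). The phosphatase gene Dusp10 fell from 5 to 2 (-0.99, adjusted p = 0.00745). Sowaha rose from 2.33 ± 0.577 to 8 ± 0 (1.45, adjusted p = 0.00414), the DNA polymerase gene Pold1 from 1.67 to 5 (1.20, adjusted p = 0.0272), the ion-channel gene Lrrc8a from 4 to 9 (1.02, adjusted p = 0.0199) and the ephrin receptor gene Epha8 from 5 to 10.7 (0.96, adjusted p = 0.0217).

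In the fit with the VDR line 0 genes rose and 1 fell by limma, against 677 at an unadjusted p under 0.05. Replicate values did not overlap in 11.9% of genes, where chance gives at most 10%. Without tumor replicate 1 the count was 3 and without tumor replicate 3 it was 2, and other settings gave between 1 and 170, with 10 up and 0 down at 50000 summits and 0 up and 10 down in the whole lists. The Hedgehog list had 0 up and 1 down of 19, or 1 up and 1 down adjusted over the list alone, and the 16 other lists had 0 in either direction. Adjusted over the list alone, 2 AP-1 genes, 1 microglia gene and 2 non-granule lineage genes fell and 1 astrocyte gene rose. No list passed camera, with adjusted p = 0.12 for AP-1 and 0.127 for non-granule lineages. Astrocyte genes had a median below 0 with a mean and test above it, and Purkinje and interneuron genes a mean above 0 with a median and test below it.

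From hyperplasia to tumor 1889 regions were gained and 2107 lost, or 2731 and 1053 at a score of at least 10. Gained regions lay 23799 bp from the sulfotransferase gene Chst15 at chromosome 7, 132211730 to 132212229, away from any gene at chromosome 7, 61837270 to 61837769, and in the fibulin gene Fbln2 at chromosome 6, 91218719 to 91219218. Lost regions lay in the DNA-repair gene Tdp1 at chromosome 12, 99929211 to 99929710, 4817 bp from Ctr9 at chromosome 7, 111023884 to 111024383, and in Lrrc28 at chromosome 7, 67608300 to 67608799. The total of 3996 was 6200 without tumor replicate 1, 6132 without hyperplasia replicate 2 and 7163 without hyperplasia replicate 3, as fewer libraries had to match.

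The comparison of tumor with GNP spans the whole course. Here too, age cannot be told apart from stage, since no age is listed for the tumor libraries. Hpgds had 5 ± 1 regions against 0.333 ± 0.577 in GNP, Kif21a 7.67 ± 0.577 against 1 ± 0, and Pid1 9 ± 1 against 2 ± 0. The axon-guidance gene Sema3e rose from 3 ± 0 to 11.7 ± 2.08 and the RNA polymerase I subunit gene Polr1b from 1 ± 0 to 6 ± 0. Tumors closed chromatin over Pax3, from 7.33 ± 0.577 to 0.667 ± 1.15, over Gli3, from 11.7 ± 0.577 to 3 ± 0, over Csmd3, from 8 ± 0 to 1.33 ± 0.577, over the netrin-G ligand gene Lrrc4c, from 9.33 ± 1.53 to 1.67 ± 0.577, and over Dpp10, from 4.33 ± 0.577 to 0. Nfia (62.7 ± 9.07 against 60.7 ± 0.577, adjusted p = 0.992), Nfib (50.3 ± 7.02 against 51.7 ± 4.04, adjusted p = 0.918), Ptch1 (adjusted p = 0.7), Gli1 (adjusted p = 0.91) and Atoh1 (adjusted p = 0.391) did not pass the test.

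Further gains were at Far2 (log2 change 1.99), Eif4a3l1 (1.73), C1qtnf7 (1.44) and Epn2 (1.41), and at the forkhead gene Foxl1, which had 2.33 ± 0.577 regions and was listed at 0 in GNP. Further losses were at Nkain2 (log2 change -1.90), Cyp4f39 (-1.88), Nell1 (-1.53) and Dmrta1 (-1.48), and at Zfp982, listed at 0 in tumor. Adjusted p-values were 4.14e-05 for Kif21a, 8.31e-05 for Dpp10, 0.000131 for Gli3, 0.00134 for Csmd3, 0.00258 for Lrrc4c, 0.0035 for Pid1 and 0.00424 for Hpgds, and 0.0075 for Pax3, Sema3e and Polr1b. Far2, Foxl1, Dpp10, Cyp4f39 and Zfp982 were tested only because the VDR libraries were in the fit.

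**Figure D2:**
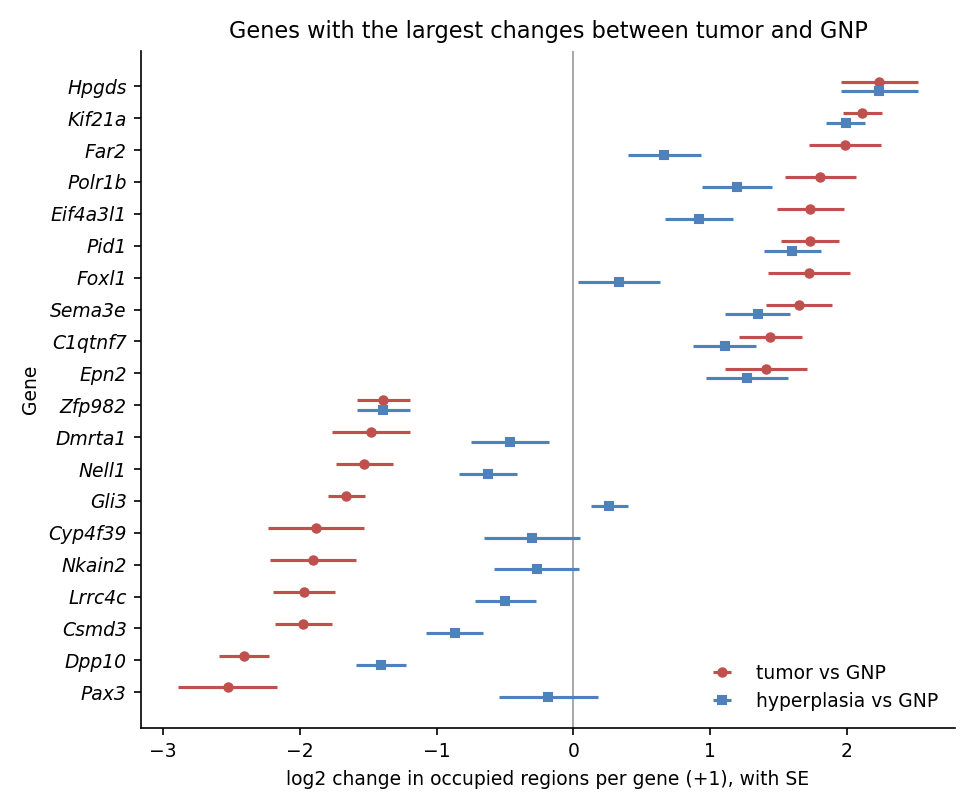
Log2 change in occupied regions per gene (horizontal axis, with SE) for 20 genes with the largest changes between tumor and GNP (vertical axis), as circles for tumor against GNP and squares for hyperplasia against GNP, n = 3 libraries per group. Kif21a reached 2.11 in tumor and 1.99 in hyperplasia, while Gli3 reached -1.66 in tumor; points for Dpp10, Foxl1 and Zfp982 depend on the pseudocount because a group was listed at 0.

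Among the fixed lists the Hedgehog pathway had 0 up and 1 down (Gli3) of 19. The AP-1 list had 0 up and 1 down of 14, Atf3, a stress-response factor (2.67 ± 0.577 against 5 ± 1, adjusted p = 0.0473), and 0 up and 2 down adjusted over the list alone. Foxp2 was the 1 Purkinje and interneuron gene of 6 to rise (19 ± 2 against 8.33 ± 1.15, adjusted p = 0.0467), and Pax3 the 1 non-granule gene of 11 to fall. Both the Atf3 and the Foxp2 call ended whichever of the GNP or tumor libraries was left out (adjusted p from 0.0853 to 0.189 and from 0.103 to 0.18). Against neighbouring genes the Atf3 change was -0.59 (adjusted p = 0.07) and the Foxp2 change 0.70 (adjusted p = 0.12). The other 13 lists had 0 genes in either direction, though adjusted over the list alone 1 astrocyte gene, 1 microglia gene and 1 non-granule gene rose. No list passed camera, with a lowest adjusted p of 0.371.

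Gained regions with the highest rank were the one in Eif4g3 given above, one in the clotting-factor gene Vwf at chromosome 6, 125597833 to 125598332, and one in the dynamin gene Dnm1 at chromosome 2, 32342402 to 32342901. Lost regions were those on chromosome 12 and chromosome 7 already lost in hyperplasia, and one 745 bp from the Wnt receptor gene Fzd8 at chromosome 18, 9211861 to 9212360. In all 4759 regions were gained and 4409 lost, or 2838 and 5422 at a score of at least 10. Across the 3 stages, 2093 regions were unoccupied only in GNP, and 0.0119 of the 1680 arrangements of the 9 libraries gave as many. Another 2394 were occupied only in GNP (share 0.0119), 786 only in tumor (0.0357) and 1245 only in hyperplasia (0.0238). Unoccupied only in tumor were 450 (0.0357), and only in hyperplasia 630 (0.0238). Each count depends only on which 3 libraries are set apart, so 0.0119 is the smallest share possible. The larger shares only rank the stages among themselves. Of regions gained in tumor over GNP, 10.9% had no summit in the whole GNP lists. For those gained over hyperplasia, 3.49% had none in the whole hyperplasia lists. Of regions lost in tumor, 9.96% and 9.78% had none in the whole tumor lists.

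By limma 69 genes rose and 36 fell, against 1091 at an unadjusted p under 0.05. Replicate values did not overlap in 22.0% of genes, where chance gives at most 10%. The count of 105 was 38 in the whole lists, which shared 10 of them and had 12 up and 26 down, and 139 at 50000 summits, which shared 14. At a score of at least 10 there were 4 up and 22 down. The count was 617 in the fit of primary libraries alone. It was 31, 26 and 21 without GNP replicate 1, 2 or 3 and 31, 26 and 34 without tumor replicate 1, 2 or 3. Of the 22 called genes named here, 14 stayed called whichever library was left out; the others were Atf3, C1qtnf7, Cyp4f39, Dmrta1, Epn2, Foxl1, Foxp2 and Nkain2.

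Chromosome 6 stood out in tumor. It held 20 of the 69 genes that rose, or 29.0%, against 6.46% of the genes tested, among them Hpgds, Far2, Eif4a3l1 and Foxp2. It took 6.70 ± 0.608% of tumor summits, against 5.13 ± 0.0692% in GNP and 5.25 ± 0.0668% in hyperplasia (exact permutation p = 0.00714, adjusted p = 0.15), and each tumor library lay above all 6 others. In VDR cells it took 9.08 ± 1.02% untreated, 8.18 ± 1.00% with siNC, 8.0% with siNfia and 7.68% with siNfib. Leaving out chromosome 6 gave 39 genes up and 30 down between tumor and GNP.

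Untreated VDR cells were compared with tumor to set the cell line beside the tissue it models. The untreated lists were the weakest, with a score at rank 100000 of 3.86 against 14.4 in tumor. Losses in the line therefore cannot be told apart from weak signal. The 10 genes with the largest losses in the line included Dpp6, a potassium-channel partner, with 1 ± 0 regions against 17.7 ± 2.52, Nkain3, with 0.667 against 15.7 ± 0.577, and the latrophilin gene Adgrl2, with 0.667 against 13.3. The netrin receptor gene Unc5c, the protocadherin gene Pcdh7, the synaptoporin gene Synpr, Myrfl and the growth factor gene Gdf6 were listed at 0 in the line, against 9.33 ± 1.53, 9 ± 2.65, 8.67 ± 2.52, 8 ± 1 and 7.33 ± 1.53 in tumor. Granule progenitor factors were also less open, with 0 up and 14 down of 18 tested. Barhl2 had 2.67 ± 1.15 regions against 19 ± 1, Pou3f2 3 ± 2 against 17.7 ± 0.577, Meis1 6.67 ± 2.08 against 26.7 ± 2.52 and Pax6 6 ± 1.73 against 24 ± 3.61. The list passed camera (adjusted p = 0.00274) but not with the correlation estimated from the data (adjusted p = 0.471 with an estimated correlation). With siNC-treated in place of untreated cells it had 3 up and 9 down and did not pass (adjusted p = 0.717).

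All 10 genes with the largest gains in the line lay on chromosome 1, and all but Cntnap5b and Slco6d1 in one dense stretch. Dpp10 had 231 ± 62.5 regions and Cntnap5a 97.7 ± 26.1, both listed at 0 in tumor, and the scavenger receptor gene Marco had 75.7 ± 25 against 0.333 regions. The grainyhead-like factor gene Tfcp2l1 had 111 ± 16 against 1.33, Cfap221 54.3 ± 7.77 against 0.333, Cntnap5b 45.7 ± 12.7 against 0.333, and C1ql2 60.3 ± 4.73 against 2.33 ± 0.577. Slco6d1, Tmem37 and Relch had 19 ± 3, 19.3 ± 6.66 and 19 ± 7 regions and were listed at 0 in tumor. The Hedgehog factor gene Gli2, in the same stretch, had 353 ± 30.9 against 42.7 ± 3.51 (log2 change 3.02, adjusted p = 3.38e-09), but -0.46 against its neighbouring genes. Positions 103000001 to 125000000 of chromosome 1 held 5395 ± 914 of the 100000 summits kept in untreated VDR libraries, against 343 in tumor, 365 in GNP and 360 in hyperplasia, and 581, 663 and 547 with siNC, siNfia and siNfib.

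**Figure D3:**
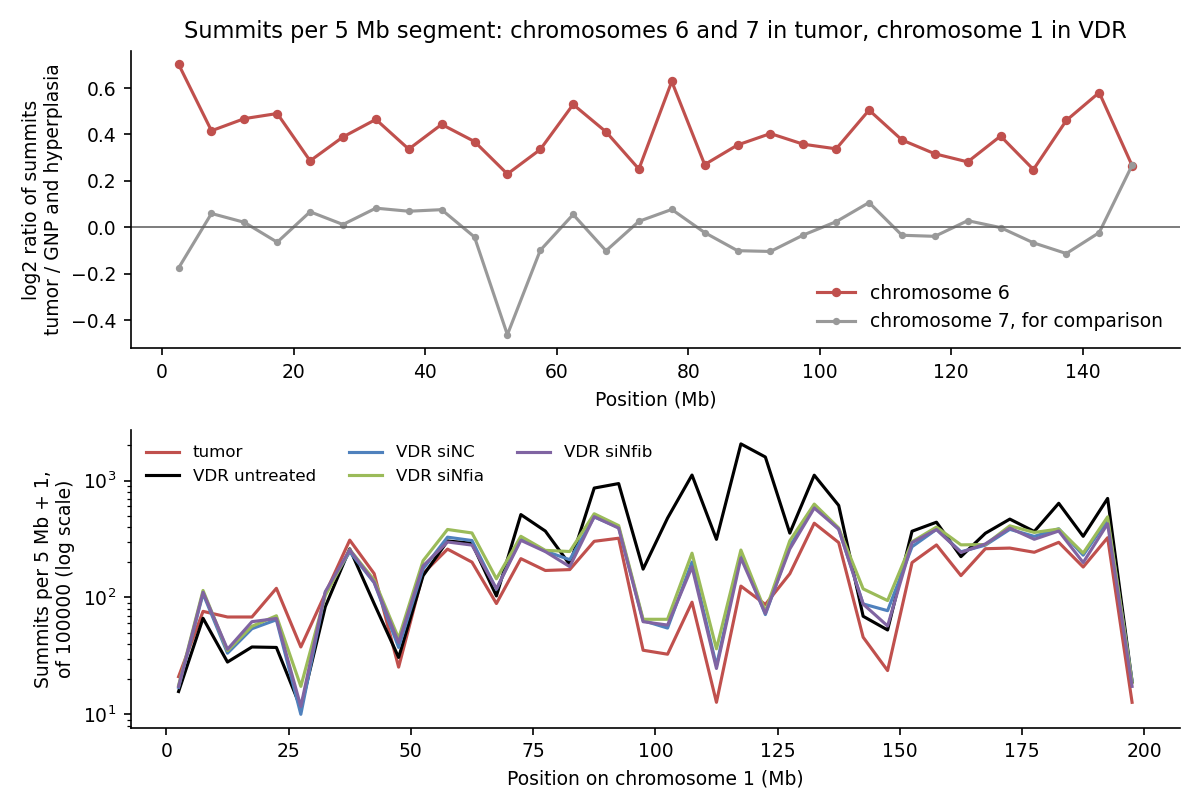
Top, log2 ratio of summits in tumor over the mean of GNP and hyperplasia (vertical axis) in segments of 5 Mb along chromosomes 6 and 7 (horizontal axis, position in Mb). Bottom, mean summits plus 1 per 5 Mb segment of chromosome 1 on a log scale, of 100000 kept, for tumor and the 4 VDR groups, n = 3 libraries each; all 30 segments of chromosome 6 lie above 0, and the stretch from 103000001 to 125000000 of chromosome 1 held 5395 summits in untreated VDR cells against 343 in tumor.

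Of the NFI family, 2 of 4 rose and 2 fell. Nfia had 29.7 ± 8.74 regions in the line against 62.7 ± 9.07 in tumor (log2 change -1.09, adjusted p = 0.00026) and Nfic 12.3 ± 4.93 against 23.3 ± 1.53 (-0.93, adjusted p = 0.00292). Nfib rose from 50.3 ± 7.02 to 62.3 ± 7.51 (0.31, adjusted p = 0.0359) and Nfix from 37 ± 1.73 to 46.3 ± 4.04 (0.31, adjusted p = 0.0246). The direction of both rises turned in the whole lists (-0.20 for Nfib, -0.22 for Nfix), at a score of at least 10 (-2.34 and -1.83) and against neighbouring genes (-0.50 and -0.40). In the Hedgehog list 4 rose and 10 fell of 19. The co-receptor gene Cdon fell from 8 ± 1 to 0.667 ± 0.577 (adjusted p = 4.43e-06), Ptch1 from 19.7 ± 3.06 to 13 ± 1 (adjusted p = 0.00363) and Gli1 from 6.67 ± 0.577 to 4 ± 1 (adjusted p = 0.00403), though against neighbouring genes the changes were 0.17 for Ptch1 and 0.014 for Gli1. Atoh1 fell from 12.3 ± 2.08 to 9 ± 1 (-0.41, adjusted p = 0.0257), but with siNC-treated cells in place of untreated ones it rose by 0.50, on a chromosome, 6, whose share of summits was also higher in siNC than in tumor libraries. The Atoh1 call ended without tumor replicate 1 or 2 or VDR replicate 1 (adjusted p = 0.103, 0.0835 and 0.0708). That of Nfib ended without tumor replicate 1 or 2 or VDR replicate 1 or 3 (adjusted p = 0.153, 0.0663, 0.0744 and 0.132), and that of Nfix without tumor replicate 1 or 3 or VDR replicate 1 or 2 (adjusted p = 0.0684, 0.0695, 0.081 and 0.0582).

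Of granule neuron genes 6 rose and 12 fell of 24 (7 and 12 adjusted over the list alone). The counts were 4 up and 2 down of 10 for the cell cycle, 2 and 4 of 11 for tumour suppressors, 5 and 3 of 14 for AP-1 and 2 and 4 of 10 for neural stem genes. For markers of other cells they were 1 and 3 of 6 for astrocytes, 1 and 4 of 6 for oligodendrocytes (2 and 4 adjusted over the list alone), 1 and 1 of 3 for microglia, 2 and 2 of 6 for endothelium and 1 and 3 of 6 for Purkinje cells and interneurons. Fibroblast genes had 4 up and 4 down of 11 (5 and 4 adjusted over the list alone), non-granule selectors 3 and 3 of 11, Hox genes 1 and 0 of 1, and chromatin regulators 2 and 7 of 15 (3 and 7 adjusted over the list alone). The cell cycle, AP-1, microglia and non-granule lists had a median below 0 but a mean and test above it, and none of the lists in this paragraph passed camera.

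Regions gained in the line lay in Kctd16 at chromosome 18, 40307974 to 40308473, 92598 bp from the cadherin gene Cdh7 at chromosome 1, 109889389 to 109889888, and 13252 bp from Mob3b at chromosome 4, 34935572 to 34936071. Lost regions lay 45219 bp from Tank at chromosome 2, 61533088 to 61533587, away from any gene at chromosome 16, 5672851 to 5673350, and 86151 bp from the transcription factor gene Maf at chromosome 8, 115616852 to 115617351. In all 2350 regions were gained and 18334 lost. Chromosome 1 held 886 of the gained regions, or 37.7%, and 4.89% of the lost ones. By limma 1782 genes rose and 2252 fell, against 4338 at an unadjusted p under 0.05. Calls differed between whole chromosomes, with 372 up and 40 down on chromosome 1, 222 and 44 on 8, and 224 and 15 on 15. Chromosome 17 had 210 and 29 and chromosome 4 had 153 and 115, but chromosome 13 had 3 and 154 and chromosome 18 had 1 and 100. Without centring on neighbouring genes, a change at a gene or list therefore cannot be told apart from one along its chromosome. Replicate values did not overlap in 51.8% of genes, where chance gives at most 10%, and the median change over all genes was -0.14. Counting against neighbouring genes gave 2405, and 50000 summits gave 1769. At a score of at least 10, which keeps few summits of the weak untreated lists, 4 rose and 6123 fell.

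Because the untreated libraries were the weakest and least alike, the line was also set against tumor with siNC-treated cells, an alternative chosen after the data were seen. It gave 5420 regions gained and 12562 lost, and 1105 genes up and 2002 down of 6760.

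The siNC comparison shows what libraries of control siRNA-treated and untreated cells differ in. The untreated lists were weaker, with a score at rank 100000 of 3.86 against 6.84. Differences in signal strength therefore cannot be told apart from differences in chromatin. Cells given control siRNA had more occupied regions over granule progenitor genes, with 11 up and 0 down of 17 (12 and 0 adjusted over the list alone). Zic4 had 30 ± 4.36 regions against 6.67 ± 1.53 in untreated cells, Zic1 14 ± 1 against 3 ± 1, Pou3f2 9.33 ± 0.577 against 3 ± 2, Meis1 19.7 ± 0.577 against 6.67 ± 2.08 and Atoh1 17.7 ± 0.577 against 9 ± 1. The list passed camera (adjusted p = 4.15e-05), but not with the correlation estimated from the data (adjusted p = 0.284 with an estimated correlation). Among single genes the Hippo effector Yap1 rose from 0.667 ± 1.15 to 5.33 ± 0.577 (adjusted p = 0.000395), the thyroid hormone receptor gene Thrb from 1.33 ± 1.53 to 8.67 ± 1.53 (adjusted p = 0.000374) and the actin nucleator gene Cobl from 2 ± 1.73 to 12.3 ± 1.15 (adjusted p = 3.81e-05).

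Further gains were at the acetyltransferase gene Kat6a, with 4.67 ± 1.53 regions and listed at 0 untreated, at Hs3st5 (log2 change 2.25), Lhfpl3 (2.12) and Hmgcll1 (2.06), and at the histone genes H4bc24 (2.24) and H2bc13 (2.06). The 10 largest losses were again on chromosome 1, all but Cntnap5b in the dense stretch. Dpp10 had 1 ± 1 regions against 231 ± 62.5, the homeobox gene En1 0.667 ± 0.577 against 67 ± 18.5 and Insig2 2.33 ± 0.577 against 56.3 ± 12.4, while Cfap221 and Cntnap5b had log2 changes of -4.59 and -4.50. Cntnap5a, Marco, C1ql2, Tmem37 and B020011L13Rik were listed at 0 with siNC. Gli2 had 65 ± 7.81 against 353 ± 30.9 regions (log2 change -2.43, adjusted p = 8.59e-09), but 0.28 against its neighbours.

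Nfia had 50 ± 2.65 regions with siNC against 29.7 ± 8.74 untreated (adjusted p = 0.0025) and Nfib 94 ± 21.9 against 62.3 ± 7.51 (adjusted p = 0.00895), the latter with a change of -0.034 at 50000 summits. Nfix fell from 46.3 ± 4.04 to 35 ± 2 (adjusted p = 0.0069), though the change was 0.94 at a score of at least 10 and 0.016 against neighbours. The NFI list had 2 up and 1 down of 4. Ptch1 (16 ± 2 against 13 ± 1, adjusted p = 0.116) and Gli1 (5.33 ± 0.577 against 4 ± 1, adjusted p = 0.196) did not pass the test, and the Hedgehog list had 2 up and 4 down of 15 (3 and 4 adjusted over the list alone). The counts were 10 and 7 of 22 for granule neuron genes (10 and 8 adjusted over the list alone), 3 and 2 of 10 for the cell cycle, 2 and 2 of 10 for tumour suppressors, 1 and 3 of 11 for AP-1 and 2 and 1 of 11 for neural stem genes (1 and 1 adjusted over the list alone). They were 0 and 1 of 4 for astrocytes, 0 and 1 of 5 for oligodendrocytes, 0 and 2 of 2 for microglia, 0 and 1 of 2 for endothelium and 1 and 1 of 5 for Purkinje cells and interneurons. Fibroblast genes had 2 up and 4 down of 11, non-granule selectors 4 and 3 of 10 (4 and 4 adjusted over the list alone), the 1 Hox gene 0 and 0 (0 and 1 adjusted over the list alone) and chromatin regulators 3 and 1 of 15 (2 and 1 adjusted over the list alone). Median and mean differed in sign for Hedgehog, granule neuron, cell cycle, neural stem, oligodendrocyte and Purkinje and interneuron genes, and none of these lists passed camera.

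Gained regions lay 7678 bp from Igdcc3 at chromosome 9, 65194459 to 65194958, in the neuregulin gene Nrg1 at chromosome 8, 32290087 to 32290586, and in Mamld1 at chromosome X, 71049802 to 71050301. Lost regions lay in Elfn2 at chromosome 15, 78670108 to 78670607, away from any gene at chromosome 17, 45873430 to 45873929, and 87922 bp from Ssbp2 at chromosome 13, 91372133 to 91372632. There were 7247 regions gained and 1399 lost, and the total of 8646 became 15389, 13244 and 16485 without untreated replicate 1, 2 or 3. Chromosome 1 held 650 of the lost regions, or 46.5%, and 6.03% of the gained ones. By limma 1254 genes rose and 1501 fell of 6613, against 3311 at an unadjusted p under 0.05. Here too calls differed between whole chromosomes, with 34 up and 314 down on chromosome 1 and 28 and 189 on 17. Chromosome 14 had 90 and 6, chromosome 13 had 93 and 5, and chromosome 11 had 67 and 57. Replicate values did not overlap in 38.0% of genes, where chance gives at most 10%. At a score of at least 10, 3562 rose and 1 fell, and in the whole lists 2351 rose and 1282 fell. Counting against neighbouring genes gave 1696, and all 28 named calls held whichever library was left out.

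Knockdown of Nfia was compared with control siRNA to ask what this factor does to open chromatin in the line. The siRNA acts on RNA, so region counts over the targeted genes do not check the knockdown. Nfia itself had 50.7 ± 1.53 regions against 50 ± 2.65 and Nfib 90.3 ± 9.02 against 94 ± 21.9. Atoh1 had 16 ± 4.58 against 17.7 ± 0.577, Ptch1 16.3 ± 1.53 against 16 ± 2 and Gli1 5 ± 1 against 5.33 ± 0.577. Among the genes with the smallest p, the myosin gene Myo7a had 4 ± 1 against 1 ± 0, Lrrc38 5 ± 0 against 2 ± 0 and the polarity gene Crb2 14.3 ± 2.52 against 6.67 ± 1.15 (each adjusted p = 0.163). The kinase gene Src had 1 ± 0 against 3 ± 0 (adjusted p = 0.0611), Rph3al 4.67 ± 0.577 against 10.3 ± 0.577 (adjusted p = 0.163) and Flvcr2 3.67 ± 0.577 against 8 ± 1 (adjusted p = 0.175).

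By limma 0 genes rose and 0 fell, with 425 at an unadjusted p under 0.05. Replicate values did not overlap in 7.61% of genes. Chance gives at most 10%, and less with tied counts, so whether this share is below chance cannot be said. Without siNfia replicate 2 the count was 1, and fitting the 9 siRNA libraries alone called 2, Lrrc38 up (adjusted p = 0.0245) and the RNA helicase gene Ddx5 down (2 ± 0 against 4 ± 0, adjusted p = 0.00103). Ddx5 was chosen after its values were seen. Counts of both genes were small and did not vary within siNfia or siNC, so these p-values measure no spread between those replicates. All 17 lists had 0 genes in either direction, though adjusted over the list alone 1 microglia gene and 1 Purkinje and interneuron gene fell, and the lowest adjusted p by camera was 0.696. Median and mean differed in sign for granule neuron, cell cycle and astrocyte genes. In simulated data the same comparison found 55.2% of genes changed by a fold of 2 and 16.4% of those changed by a fold of 1.5, so most changes of the latter size would be missed.

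Between siNfia and siNC libraries 1123 regions were gained and 957 lost, or 1100 and 2292 in the whole lists. Single regions were not tested, and the highest other split of these libraries gave 920 in total. Of the gained regions 11.7% had no summit in the whole siNC lists, and of the lost ones 14.6% had none in the whole siNfia lists. Whether the Nfia siRNA moved regions therefore cannot be said. Gained ones lay in Rai14 at chromosome 15, 10648338 to 10648837, and away from any gene at chromosome 3, 66398709 to 66399208. Lost ones lay 3150 bp from Cyth4 at chromosome 15, 78624919 to 78625418, in the helicase gene Ddx31 at chromosome 2, 28882909 to 28883408, and in Igsf21 at chromosome 4, 140044043 to 140044542. The total of 2080 became 3806, 3788 and 3937 without siNfia replicate 1, 2 or 3 and 3662, 3603 and 3982 without siNC replicate 1, 2 or 3.

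With the Nfib siRNA 11 genes were called, but 0 of these calls held whichever library was left out. The targeted gene Nfib had 89.7 ± 10.7 regions against 94 ± 21.9 with control siRNA and Nfia 50 ± 2.65 in both. Chromatin opened over the olfactomedin gene Olfml2a, from 1 ± 0 to 4.67 ± 0.577 regions (log2 change 1.5, adjusted p = 0.0132), over the pluripotency factor gene Nanog, from 1.67 ± 0.577 to 6 ± 0 (1.42, adjusted p = 0.0421), and over the T-cell receptor zeta-chain gene Cd247, from 3.67 ± 1.15 to 9.67 ± 0.577 (1.22, adjusted p = 0.0421). It closed over Zfp618, a zinc-finger gene, from 12.3 ± 3.21 to 4.33 ± 0.577 (-1.30, adjusted p = 0.0355), over the Ras exchange factor gene Rasgrf1, from 10.7 ± 1.15 to 4.67 ± 0.577 (-1.04, adjusted p = 0.0421), and over 9930104L06Rik, from 4.67 ± 0.577 to 1 ± 0 (-1.5, adjusted p = 0.00695).

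The ketone-metabolism gene Oxct1 and Spag1 also rose (log2 changes 1.19 and 1.28, adjusted p = 0.0445), as did the bile-acid enzyme gene Akr1d1 (1.07, adjusted p = 0.0421), while Dhrs2 (-1.64, adjusted p = 0.0445) and D630003M21Rik (-0.76, adjusted p = 0.0421) fell. The last had changes of 0.028 in the whole lists and 0.082 at a score of at least 10. Ptch1 (14.7 ± 1.53 against 16 ± 2), Gli1 (5.33 ± 1.53 against 5.33 ± 0.577) and Atoh1 (18 ± 1 against 17.7 ± 0.577) were not called. All 17 lists had 0 genes in either direction, but 3 of 11 fibroblast genes fell adjusted over the list alone (camera adjusted p = 0.101, and adjusted p = 0.881 with an estimated correlation). Median and mean differed in sign for granule neuron, cell cycle and neural stem genes.

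By limma 6 genes rose and 5 fell, against 686 at an unadjusted p under 0.05. Replicate values did not overlap in 13.1% of genes, where chance gives at most 10%. The count of 11 was 5, 2 and 4 without siNC replicate 1, 2 or 3, and 0, 0 and 0 without siNfib replicate 1, 2 or 3, so 0 of the 11 named calls held whichever library was left out. It was 1 in the whole lists and 32 with 50000 summits, each sharing 0 of the 11, 0 with 150000 summits and 85 when only the 9 siRNA libraries were fitted.

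Regions changed more widely, with 3607 gained and 2343 lost, or 7222 and 1787 in the whole lists. Gained ones lay in Zfp957 at chromosome 14, 79214927 to 79215426, away from any gene at chromosome 6, 143367794 to 143368293, and in the Sox factor gene Sox5 at chromosome 6, 144480976 to 144481475. Of the lost ones, 2 lay in C2cd4b at chromosome 9, 67754584 to 67755083 and 67717106 to 67717605, and 1 in the phosphatase gene Ptprm at chromosome 17, 67011761 to 67012260. The knockdowns shared 332 lost regions, where 50.4 would be shared by independent sets, and 252 gained ones, where 131.9 would. That expectation leaves out that both comparisons used the same control libraries. At 50000 summits 140 gains were shared, where 107.8 would be by independent sets, and 255 losses, where 48.0 would be. In the whole lists 260 gains were shared, where 61.2 would be. The 332 shared losses became 812, 757 and 882 without siNC replicate 1, 2 or 3, 509 without siNfia replicate 3 and 503 in the whole lists. With untreated cells in place of siNC for siNfib, 21 losses were shared, where 37.3 would be by independent sets, and 167 gains, where 428.6 would be.

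Regions gained or lost in tumor over GNP were followed in the siRNA-treated cells. Of regions lost in tumor, 21 ± 0.974% were occupied with siNC, 19.2 ± 0.564% with siNfia and 23.8 ± 0.146% with siNfib (exact permutation p = 0.00357, adjusted p = 0.0179). Of regions gained in tumor, 29.0 ± 1.57%, 29.5 ± 0.476% and 26.9 ± 0.202% were occupied (exact permutation p = 0.0607, adjusted p = 0.136). Relative to regions shared by all GNP and tumor libraries, of which 75.8 ± 2.69%, 72.7 ± 0.881% and 75.5 ± 0.776% were occupied, both sets differed between treatments (exact permutation p = 0.00357, adjusted p = 0.0179 for each). The relative occupancy of gained regions was 38.3% with siNC, 40.6% with siNfia and 35.6% with siNfib, and that of lost regions 27.7%, 26.5% and 31.6%. Each pair of treatments could reach no exact two-sided permutation p below 0.1. The means for tumor-lost regions ranked as the mean score at rank 100000 did, 5.92 for siNfia, 6.84 for siNC and 11.3 for siNfib. A difference between treatments therefore cannot be told apart from one in list strength. In the whole lists the difference of siNfib from siNC for tumor-gained regions turned from -2.15 to 3.45 percentage points, while that for lost regions was 6.12.

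**Figure D4:**
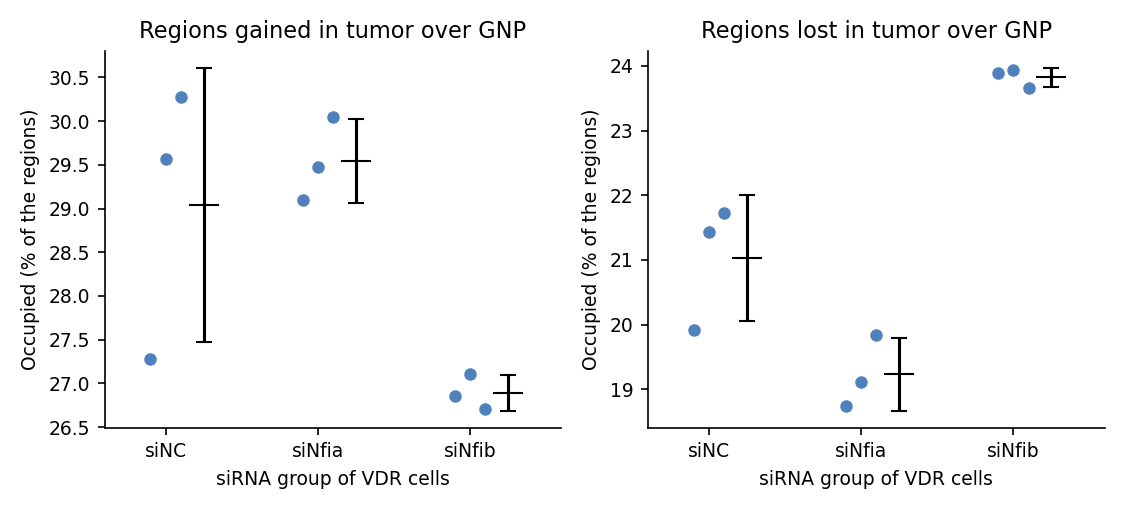
Percentage of regions gained (left) or lost (right) in tumor over GNP that were occupied in siRNA-treated VDR cells (vertical axes), by treatment (horizontal axes), with 1 point per library and bars for mean and SD, n = 3. For lost regions siNfib libraries averaged 23.8%, above siNC at 21% and siNfia at 19.2%; for gained regions the means were 26.9%, 29.0% and 29.5%.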

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

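The gene test of siNfib against siNfia libraries and the test without siNC replicate 1 were chosen only after the result was seen.

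The libraries of the 2 knockdowns differed at 37 genes when siNfib was tested directly against siNfia by limma. Of 6613 tested, 17 had more and 20 fewer regions in siNfib, with 815 at an unadjusted p under 0.05. Centring on neighbouring genes gave 39, but no library was left out and no other number of summits was tried. The siNfib lists were stronger, with a score at rank 100000 of 11.3 against 5.92 for siNfia. A difference in knockdown effects therefore cannot be told apart from one in list strength. The kinase gene Src had 4 ± 0 regions with siNfib, 1 ± 0 with siNfia and 3 ± 0 with siNC (SD, n = 3 libraries; log2 change between knockdowns 1.32, adjusted p = 0.00275). Src counts were small and did not vary within any of these groups, so this p-value measures no spread between their replicates. The other genes in this paragraph were chosen after their values were seen. The transcriptional cofactor gene Eya2 had 6 ± 1 with siNfib, 1.67 ± 1.15 with siNfia and 4.67 ± 0.577 with siNC, and Olfm2 had 9.67 ± 0.577, 3 ± 1 and 6 ± 1. The nuclear receptor gene Pparg had 1.33 ± 0.577, 5.67 ± 0.577 and 4 ± 0, and the collagen gene Col14a1 4 ± 1, 11.7 ± 0.577 and 7.33 ± 2.52. Rasgrf1, which fell with siNfib, had 4.67 ± 0.577 with siNfib and 11.7 ± 1.15 with siNfia (adjusted p = 0.0272), and Prdm16 had 3 ± 0 and 6.33 ± 0.577 (adjusted p = 0.0399). Across genes, the log2 changes of both knockdowns correlated at 0.36, where simulated unchanged groups sharing the same controls gave 0.50. The covariance was 0.0288, against 0.0287 in that simulation, so the lower correlation does not show opposed effects. Genes are not independent replicates.

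More regions differed between siNfib and siNC, 5950, than between siNfia and siNC, 2080. A weak siNC replicate 1 is argued against, since without it the siNfib count was still 2.28 times the siNfia count. A change common to both siRNAs that siNfib alone shows in full stays open: siNfib and siNfia differed by 6352 regions, where the highest other split of those libraries gave 689, but the bound set for that test was wrong, because a weaker siNfia effect would itself set these groups apart. Stronger lists in siNfib cannot be told apart from a true difference: the 1 siNC or siNfia library as strong as the weakest siNfib library, which had a score of 8.25 at rank 100000, reached a Jaccard index of 0.671 with siNfib against a lowest index of 0.711 within siNfib, but 1 library cannot decide. A difference between what Nfia and Nfib do in these cells, and a difference in how well the siRNAs worked, stay open and were not tested.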

How the results depend on the processing

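Centring on neighbouring genes, leaving out chromosome 6, siNC-treated in place of untreated cells, the fits of 9 libraries and leaving out libraries from the knockdown overlap were tests chosen only after the results were seen.

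Of 193 values of comparison results under other settings 107 stayed within the spread or within 1.5 times, and 86 moved. Of 1791 values of named genes 1511 kept direction and side of the threshold, 199 lost the call, 10 gained one, 52 uncalled values moved and 19 reversed, where a change of sign between values that both missed the threshold is not counted as a reversal. With 1 library left out, 715 of 916 values of named genes kept direction and call, 181 lost the call and 0 reversed. Read depth is unknown, and the weak lists of untreated VDR cells limit what scores of at least 10 can show. Alternatives for sequence motifs were not run. Where fewer or more genes were tested or another number of libraries was required, the count moves by construction, and for the other changes the cause was not tested.

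Counts of changed genes moved as follows. For hyperplasia against GNP the count of 138 was 5 in the whole lists, 296 without a filter on low genes, 76 with the replicate block and 728 with only the 9 primary libraries. For tumor against hyperplasia the count of 1 was 10 at 50000 summits, 12 at 150000, 10 in the whole lists, 3 at a score of at least 10, with a pseudocount of 0.5, with the block and with centring on neighbours, 89 without the filter and 170 with the primary libraries alone. For tumor against GNP the count of 105 was 169 at 150000 summits, 38 in the whole lists, 26 at a score of at least 10, 326 without the filter, 40 with the block, 69 without chromosome 6 and 617 with the primary libraries alone. For untreated VDR against tumor 4034 became 1769 at 50000 summits, 6127 at a score of at least 10, 7316 without the filter and 2405 with centring. For siNC against untreated 2755 became 1112 at 50000 summits, 4276 without the filter and 1696 with centring. For siNfia against siNC 0 became 1 with a window of 1000 bp, with a distance of 20 kb and with a pseudocount of 0.5, 29 without the filter and 2 with the 9 siRNA libraries alone. For siNfib against siNC 11 became 32 at 50000 summits, of which 0 were among the 11, 0 at 150000 and at a score of at least 10, 1 in the whole lists, 20 with a window of 1000 bp, 4 at 20 kb, 6 with a pseudocount of 0.5, 7 with the square root, 47 without the filter, 4 with the block, 27 with centring and 85 with the siRNA libraries alone. The balance of directions shifted at a score of at least 10 and in the whole lists, where list lengths differ: 4 up and 128 down at that score for hyperplasia against GNP, 4 and 22 there and 12 and 26 in the whole lists for tumor against GNP, 4 and 6123 for untreated VDR against tumor, and 3562 and 1 there and 2351 and 1282 in the whole lists for siNC against untreated. The replicate block has little meaning, since replicate numbers did not pair libraries.

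The number of fixed lists past camera went from 1 to 0 with an estimated correlation for untreated VDR against tumor and for siNC against untreated. With centring on neighbours it went from 1 to 2 for untreated VDR against tumor, where the NFI family joined (adjusted p = 0.0192; uncentred, adjusted p = 0.853 with an estimated correlation), and from 0 to 1 for siNfib against siNC, where the fibroblast list passed (adjusted p = 0.0191; uncentred, adjusted p = 0.881 with an estimated correlation). Centred values were not tested with an estimated correlation.

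Totals of gained and lost regions at 50000 summits were 5855 for hyperplasia against GNP, 2607 for tumor against hyperplasia, 5604 for tumor against GNP, 9742 for untreated VDR against tumor, 3219 for siNC against untreated, 1330 for siNfia and 3847 for siNfib. Requiring 2 of 3 libraries gave 18156, 11226, 16951, 41688, 27520, 8185 and 13253 in that order. Requiring absence from the whole lists gave 1444, 272 and 956 for the primary comparisons, 5077 for siNC against untreated, 271 for siNfia and 1366 for siNfib. The whole lists gave 44862 for untreated VDR against tumor, 16857 for siNC against untreated, 3392 for siNfia and 9009 for siNfib. At 150000 summits untreated VDR against tumor gave 31776, and at a score of at least 10 it gave 43996 and siNfia 875. At that score 2651 regions were gained and 9542 lost for hyperplasia against GNP, 2731 and 1053 for tumor against hyperplasia, 2838 and 5422 for tumor against GNP and 360 and 515 for siNfia, while the whole lists gave 1100 and 2292 for siNfia.

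The siNfia difference from siNC in tumor-gained regions was -1.02 percentage points at 50000 summits and -0.673 in the whole lists, and that of siNfib 3.45 in the whole lists. In tumor-lost regions siNfia gave -2.81 in the whole lists, and siNfib 1.62 at 50000 summits and 6.12 in the whole lists. Shared knockdown losses were 503 in the whole lists and 21 with siNfib set against untreated cells. The difference between tumor and GNP in sites at gene ends was -3.27 at 50000 summits and -0.976 in the whole lists, and that of siNfia from siNC 1.56 in the whole lists.

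Reversed values of named genes were 0.33 for Dpp10 in hyperplasia against GNP at 50000 summits. In untreated VDR against tumor they were -1.0 for C1ql2 at a score of at least 10, -0.22, -1.83, -0.40 and -0.079 for Nfix in the whole lists, at a score of at least 10, with centring and with siNC-treated cells, -0.20, -2.34 and -0.50 for Nfib under the first 3 of these, -0.46 for Gli2, 0.014 for Gli1 and 0.17 for Ptch1 with centring, and 0.50 for Atoh1 with siNC-treated cells. In siNC against untreated they were -0.034 for Nfib at 50000 summits, 0.94 and 0.016 for Nfix at a score of at least 10 and with centring, and 0.28 for Gli2 with centring. In siNfib against siNC they were 0.028 and 0.082 for D630003M21Rik in the whole lists and at a score of at least 10. The cause was not tested.

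With 1 library left out, gene counts ran from 16 to 33 for hyperplasia against GNP, 1 to 3 for tumor against hyperplasia, 21 to 34 for tumor against GNP, 3572 to 4181 for untreated VDR against tumor, 2131 to 2891 for siNC against untreated, 0 to 1 for siNfia and 0 to 5 for siNfib. Region totals in that order ran from 10861 to 13151, 5502 to 7163, 10731 to 11981, 23077 to 29525, 10634 to 16485, 3603 to 3982 and 7595 to 8646. The excess of similarity within groups ran from 0.0858 to 0.122 for primary and 0.0411 to 0.0857 for siRNA libraries. Differences in tumor-gained regions ran from -0.378 to 1.12 for siNfia and -3.03 to -1.53 for siNfib, and in tumor-lost regions from -2.35 to -1.44 and 2.24 to 3.15. Shared losses ran from 379 to 882, and the excess on chromosome 6 from 1.28 to 1.86 points. Differences in sites at gene ends ran from -2.67 to -2.14 for tumor and -2.30 to -0.928 for hyperplasia against GNP, 0.552 to 2.48 for siNfib and -1.40 to 0.522 for siNfia.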

Other observations

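The comparison of siNC-treated cells with tumor was chosen after the data were seen, as were the tests of chromosome 6, of the chromosome 1 stretch except that of extra copies, and of other splits.

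Against tumor, siNC-treated VDR cells had more open regions over the granule progenitor gene Atoh1, with 17.7 ± 0.577 regions against 12.3 ± 2.08 (SD, n = 3 libraries; log2 change 0.50, adjusted p = 0.00594 by limma), and over Zic2, with 11 ± 1 against 6.67 ± 1.15 (0.65, adjusted p = 0.00527). Atoh1 lies on chromosome 6, which took 8.18% of summits with siNC and 6.70% in tumor, and no value against its neighbouring genes was computed. They had less over Barhl2, at 7.67 ± 1.53 against 19 ± 1 (-1.22, adjusted p = 0.000149), Pax6, at 10.3 ± 1.53 against 24 ± 3.61 (-1.14, adjusted p = 7.73e-05), and the neuronal differentiation factor Neurod1, at 3 ± 1 against 7.33 ± 0.577 (-1.09, adjusted p = 0.000448). Nfib gained regions, from 50.3 ± 7.02 to 94 ± 21.9 (0.87, adjusted p = 0.00119), while Nfia went from 62.7 ± 9.07 to 50 ± 2.65 (-0.31, adjusted p = 0.014). No value against neighbouring genes was computed for Nfib either. In untreated cells its rise over tumor turned direction against its neighbours. On chromosome 4, the chromosome of Nfib, positions 81000001 to 82000000 held 206 ± 85.7 of 100000 summits with siNC and 48 ± 7 in tumor. The Nfib rise with siNC therefore cannot be told apart from a raised stretch of its chromosome. The Hedgehog factor gene Gli3 went from 3 ± 0 to 0.333 ± 0.577 (-1.67, adjusted p = 0.000389). The oligodendrocyte factor Olig2 had 0.333 ± 0.577 against 10.3 ± 0.577 (-3.17, adjusted p = 1.19e-05), the chromatin remodeller gene Chd7 10.7 against 39 (-1.78, adjusted p = 4.2e-07), and Gdf10, listed at 0 in the line, 8 in tumor. The neurotrophin receptor gene Ntrk2 and the glutamate receptor gene Gria1 were listed at 0 in the line against 16 and 10.7 in tumor. All genes in this paragraph were chosen after their values were seen. No list passed camera, with a lowest adjusted p of 0.259, and granule progenitor genes had 3 up and 9 down of 18 (4 and 10 adjusted over the list alone).

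Tumor libraries held more summits on chromosome 6 than GNP and hyperplasia libraries, by 1.51 percentage points. The limit of 100000 summits is argued against, since in the whole lists 3 of 3 tumor libraries lay above every GNP and hyperplasia library, and so are a few dense clusters, since the median segment of 5 Mb was raised by 0.383 on the log2 scale. All 30 segments were higher in tumor, against 39.2% of 462 segments on other autosomes, and the single tumor libraries had median differences of 0.495, 0.427 and 0.211. An extra copy of chromosome 6 in many tumor cells may account for this, and VDR libraries were raised too, but copy number was not measured. A change of chromatin along the whole chromosome without a gain of DNA stays open and was not tested.

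Untreated VDR libraries had dense summits between 103000001 and 125000000 of chromosome 1, 15.2 times the primary share. Whether weak signal alone accounts for this cannot be told. In the whole lists the untreated share was 5.61 times the siNC share there, but 1.07 times in a stretch of chromosome 6, a ratio of 5.25. That stretch was chosen as raised in both groups, and the ratio depends on this choice. Positions 28000001 to 29000000 of chromosome 17 held 547 summits per 100000 untreated and 275 with siNC. Positions 98000001 to 99000000 of chromosome 1 held 74.2 and 20.7. Other raised stretches of chromosome 6 were closer, such as 852 against 701 and 296 against 313. A raised stretch hidden below the limit in siRNA lists is argued against, since in the whole lists siNC libraries held at most 751 summits per 100000 there and untreated ones at least 3311. Extra copies of the stretch cannot be told apart from other causes: the lowest median rank percentile of its summits was 42.0 among the 100000 kept, but the bound set on that value was ill chosen, because the medians were 50.1 to 63.3 in the whole lists and among the strongest 10000 summits the stretch was raised 6.75 times too. A subline or a mislabelled set of untreated libraries stays open and was not tested.

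The other splits of the 6 libraries in each comparison number 10 with the real one, which cannot give a share under 0.1. For genes, the real split and the highest other gave 138 and 0 for hyperplasia against GNP, 1 and 0 for tumor against hyperplasia, 105 and 0 for tumor against GNP, 4034 and 0 for untreated VDR against tumor, 2755 and 2 for siNC against untreated, and 11 and 0 for siNfib against siNC; 1 of 10 splits gave as many in each of these, and 10 of 10 for siNfia against siNC, where all gave 0. For regions they gave 9577 and 637, 3996 and 929, 9168 and 492, 20684 and 678, 8646 and 1297, 2080 and 920 for siNfia, and 5950 and 693 for siNfib.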
